A study of Homo sapiens and Mus musculus with 48 samples.

How the data were processed

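Replication timing was measured by Repli-seq, in which cells are pulsed with the nucleotide analogue BrdU, sorted by DNA content into early and late S phase, and the BrdU-labelled DNA of each fraction is sequenced. The series held 48 samples, 42 human and 6 mouse. Each early library and its late partner made up 1 timing track, so the samples gave 24 tracks, 21 human and 3 mouse. Tracks fell into 12 groups by cell line, protocol and number of cells, as the labels give them. Numbers of cells were given only for the optimized H9 tracks. Comparisons between lines or protocols may therefore also differ in cell number. H9 is a human embryonic stem cell line, U2OS a human osteosarcoma line and MEF stands for mouse embryonic fibroblasts. H9 cells were grown in mTeSR Plus on Geltrex, U2OS cells in DMEM with fetal bovine serum and MEFs in a DMEM and F10 medium, per the labels' protocols.

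The authors deposited 4 tables of log2 ratios of early over late signal, 1 value per track and 10-kb position. The base of the logarithm was not given in the file headers; the protocols cited in the labels define timing as a log2 ratio, and differences are given on that scale and never turned into folds. Positive values mean replication early in S phase and negative values replication late. Reads were handled with BWA, SAMtools and bedtools and placed on hg38 or mm10, per the submitters' processing notes, which give no versions in the sources used here. Neighbouring positions held nearly equal values and most tracks had nearly the same mean and spread, so the deposited values had been smoothed and scaled; the method is not given in the sources used here. Smoothing joins neighbouring windows, so counts of windows do not count independent events, and scaling can hide part of the differences in contrast between whole tracks. Libraries were made with NEBNext Ultra or KAPA HyperPlus kits, per the labels' protocols, which do not say which sample had which kit. Read depth is unknown, because the tables hold ratios and no counts, so no counting interval is given.

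Positions were averaged in 100-kb windows of the autosomes, keeping windows with values at 50% or more of their positions in every track of a fit. Standard and optimized tracks sat in different tables, so the tracks of each fit were quantile-normalized together. Means and SDs of a group are of deposited values, while differences come from the fit after normalization. Differences were tested in each window with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over windows. A window was called at an adjusted p below 0.05 and a difference of at least 0.5. Only the groups compared entered a fit, except for the interaction of cell line and protocol, which used 4 groups. A lone track (H9 at 5000 cells, MEF by the standard protocol) was assumed to vary like the other group of its fit. Nothing in the labels says that replicate tracks came from separate cultures, so p-values measure only the spread between these tracks, which may be technical.

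Gene positions came from a RefSeq table of GRCh38.p14, the same assembly as hg38, with no strand or start sites. A gene therefore took the window of its midpoint in place of its start site, a departure from the plan. Of 19122 protein-coding autosomal genes, 19001 had a value in the standard tracks. No mouse annotation was used here, so mouse windows are given without genes. In all, 11 gene lists were fixed: pluripotency, mesenchymal and osteogenic, neural ectoderm, endoderm and liver, blood and immune, long genes of common fragile sites, housekeeping, epidermal, HOX, olfactory receptor, and zinc finger (ZNF) genes on chromosome 19. All list genes were found in the table, and all were measured except 1 pluripotency, 1 housekeeping and 7 olfactory receptor genes. Lists were tested as sets of windows with camera at a preset correlation of 0.01 and with the estimated correlation, and with fry, with adjustment over the 11 lists of a comparison. Genes of a list that share a window share its value, so counts of genes are not counts of separate tests. The 18 HOX genes lay in 9 windows, the 250 zinc finger genes in 133 and the 384 measured olfactory receptor genes in 164.

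The genes and regions named were set by rule. For each list, they were the up to 3 called members with the largest difference between H9 and U2OS and the uncalled member with the smallest. Runs of adjacent called windows of at least 500 kb gave the 5 regions per direction with the largest mean difference in the standard tracks, each with up to 2 genes. Results on a few genes are not reported here. Protocol comparisons were to name regions of at least 300 kb, and there were none. Tests, gene lists, this rule and most alternatives were fixed before the data were examined.

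Across the 14 optimized H9 tracks, 4 measures were related to the logarithm of cell number: Pearson's r with the mean of the standard H9 tracks, scatter between replicates (the SD over windows of the difference of a track from the mean of the other tracks of its group), the range from the 5th to the 95th percentile, and the SD of the step between adjacent positions. Relations were tested two-sided by permutation, with 100000 resamples or exactly where 7 or fewer values entered, and adjusted over the 4. Scatter was taken as 1 value per group, since tracks of a pair share it, a departure from the plan.

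The fits were tested on simulated data with 200 changed windows and the spread of each real window. For H9 by protocol (27071 windows), 86.5% of changes of 1 and all changes of 2 were recovered. For U2OS by protocol (27075 windows), no change of 1 and 88% of changes of 2 were. For cell lines in standard tracks (27082 windows), 49.5% of changes of 1 and 99% of changes of 2 were, against 0% and 93% in optimized tracks (27098 windows). Calls outside the changed windows were up to 12.63% of the calls for H9 by protocol and up to 12.33% for the standard cell line comparison, more than the nominal 5%.

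Alternatives were the values as deposited, scaling by median and interquartile range, other window sizes, other minimum differences, chromosome X included, less filled windows, each replicate left out, the replicate number as a block, the window set of whole gene bodies, and other percentiles and correlations for the track measures. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures drawn with matplotlib 3.10.9.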

Results

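Replication timing, the log2 ratio of early over late S-phase signal, was available as 24 tracks at 10-kb positions. The H9 tracks comprised 2 of the standard protocol and 14 of an optimized protocol run on a falling number of cells. Of these 14, 2 each came from 40000, 20000, 10000, 1000 and 500 cells, 1 from 5000 cells and 3 from 100 cells. U2OS was measured in 2 standard and 3 optimized tracks, and MEF in 1 standard and 2 optimized tracks. The human tables held 286320 optimized and 285642 standard positions, of which 285524 were shared, and mouse positions numbered 244598 and 244597. The depth of the libraries is unknown. The design asked where the stem cell and the osteosarcoma line differ in timing, whether both protocols give the same profile, and how few cells still give it. All human coordinates are on hg38.

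In the standard tracks, SOX2, a core pluripotency factor (chromosome 3, 181711925 to 181714436), replicated early in H9 at 3.26 ± 0.26 (SD, n = 2) and late in U2OS at -4.30 ± 0.09 (SD, n = 2). The fitted difference was 7.57 (SE 0.26, adjusted p = 3.43e-05). OTX2, a transcription factor of the anterior brain (chromosome 14, 56799905 to 56810479), stood at 3.81 ± 0.39 in H9 and -3.24 ± 0.00 in U2OS, a difference of 7.06 (SE 0.21, adjusted p = 2.64e-05). RUNX1, a regulator of blood and bone development (chromosome 21, 34787801 to 35049302), was late in H9 at -3.66 ± 0.01 and early in U2OS at 3.14 ± 0.33, a difference of -6.84 (SE 0.15, adjusted p = 1.91e-05). VIM, which encodes the intermediate filament of mesenchymal cells, stood at -2.06 ± 0.20 and 3.55 ± 0.00, a difference of -5.55 (SE 0.13, adjusted p = 1.96e-05). Over the autosomes, 16139 of 27082 windows were called by limma, 59.6% of them, with 8076 earlier in H9 and 8063 earlier in U2OS. Scaling by median and interquartile range in place of quantiles called 18724 windows, of which 39.3% were earlier in H9 against 50.04% of the calls here, and moved the median difference of all windows from -0.04 to -0.32.

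Adjacent called windows joined into 537 regions of at least 500 kb that were earlier in H9, with a median length of 1100 kb and a total of 742.2 Mb, and 555 that were earlier in U2OS, totalling 709.8 Mb. The largest mean difference toward H9 lay on chromosome 7 from 6900001 to 8900000, over GLCCI1 and ICA1, where the region averaged 1.88 ± 0.18 in H9 and -3.30 ± 0.00 in U2OS. GLCCI1 differed by 8.02 and ICA1, an islet autoantigen, by 7.78. The next such region, on chromosome 9 from 76800001 to 78800000 over CEP78 and VPS13A, averaged 2.84 ± 0.09 and -2.29 ± 0.03. Another region, on chromosome 19 from 19600001 to 22000000, held 26 protein-coding genes, among them LOC124904660 and ZNF486, and averaged 2.35 ± 0.16 and -2.72 ± 0.05. The OTX2 and TMEM260 region on chromosome 14 from 56300001 to 57600000 averaged 2.77 ± 0.37 and -2.11 ± 0.05, and the region of ATP8A1 and SHISA3 on chromosome 4 from 41700001 to 43200000 averaged 1.73 ± 0.11 and -3.07 ± 0.01. Toward U2OS, the region of TGFB2, a growth factor, and RRP15 on chromosome 1 from 217600001 to 219500000 averaged -4.22 ± 0.01 in H9 and 1.40 ± 0.04 in U2OS. TGFBR2, a receptor of the same pathway, lay with LOC105377015 in a region on chromosome 3 from 28600001 to 31600000 at -3.50 ± 0.02 and 1.45 ± 0.06. The region of CAST and PCSK1 on chromosome 5 from 95100001 to 97400000 averaged -2.99 ± 0.04 and 1.83 ± 0.01, that of RUNX1 and CLIC6 on chromosome 21 from 34300001 to 35900000 -1.72 ± 0.13 and 2.94 ± 0.12, and that of IRS1 and RHBDD1 on chromosome 2 from 224300001 to 228900000 -3.81 ± 0.04 and 0.78 ± 0.00.

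**Figure D1:**
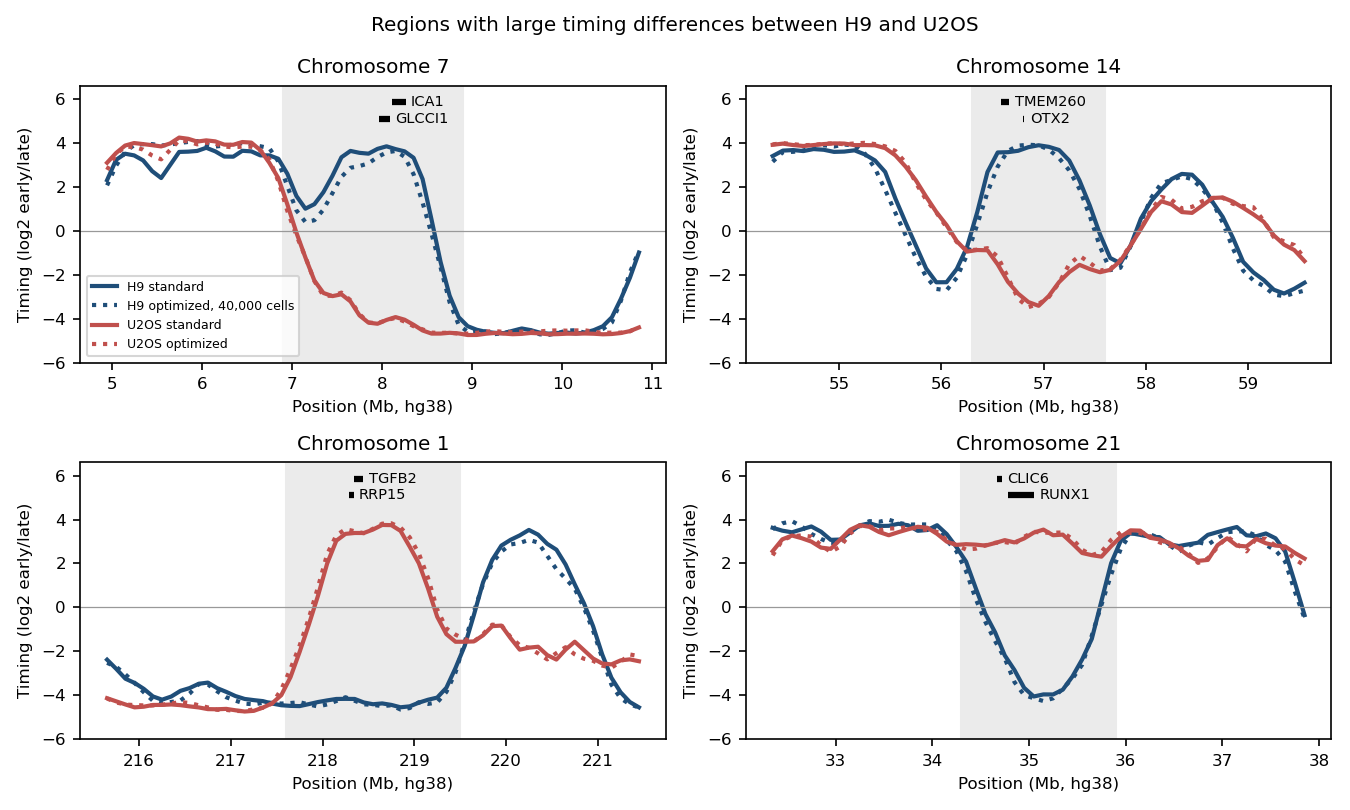
Mean replication timing (log2 early over late, vertical axis) in 100-kb windows against position (Mb, horizontal axis) around 4 of the named regions, with lines for H9 and U2OS by the standard (solid) and the optimized (dotted) protocol, the region shaded and its named genes as black bars. Over TGFB2 the H9 lines stay near -4 while both U2OS lines rise above 3, and over OTX2 the order is turned.

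Among the 27 measured pluripotency genes, 11 were earlier in H9 and 7 earlier in U2OS in the standard tracks, the same counts when adjusted over the list alone. With interquartile range scaling, the counts were 10 and 13, and without either U2OS track 10 and 4. PRDM14, a germline and stem cell regulator, differed by 6.45 (SE 0.10, adjusted p = 1.9e-05) and DPPA2 by 5.63 (SE 0.19, adjusted p = 3.11e-05), while UTF1 was at 3.28 in both lines, with a difference of 0.09 (adjusted p = 0.751). Of 28 mesenchymal and osteogenic genes, 5 were earlier in H9 and 14 earlier in U2OS, as when adjusted over the list alone. The collagen genes COL3A1 and COL5A1 differed by -5.25 and -5.03, and TGFBI by -4.99, while SPARC, which encodes a matrix protein of bone, did not pass the test at -0.18 (adjusted p = 0.59). Of 21 neural ectoderm genes, 8 were earlier in H9 and 5 earlier in U2OS, with the same counts adjusted over the list alone. The neurogenin genes went opposite ways, NEUROG2 by 4.70 (SE 0.11) and NEUROG1 by -4.70 (SE 0.11), and LHX2 stood at -0.04 (adjusted p = 0.759).

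Genes of other tissues and classes also split between the lines. Of 18 endoderm and liver genes, 8 were earlier in H9 and 7 earlier in U2OS (8 and 8 adjusted over the list alone), among them the pancreatic factor PDX1 at 5.72, APOB at -3.51 and TF, the transferrin gene, at -2.83. Their mean difference turned from 0.14 to -0.03 with interquartile range scaling. Relative to the median of all windows, the mean of each of the 11 lists kept its sign in the standard tracks under each scaling. Of 21 blood and immune genes, 4 were earlier in H9 and 7 in U2OS, as when adjusted over the list alone, and 2 and 13 with interquartile range scaling. PTPRC, the CD45 gene, differed by -5.77 and CD34 by -3.20, and SPI1 stood at 0.02 (adjusted p = 0.899), or -0.57 with interquartile range scaling. Of 18 epidermal genes, 2 were earlier in H9 and 9 in U2OS, the same adjusted over the list alone (1 and 9 without U2OS replicate 1), with the neighbours FLG and FLG2 at -4.87 and IVL at -3.02. The 18 HOX genes lay in only 9 windows. Of these genes, 10 were earlier in H9 and 0 earlier in U2OS by limma, the same adjusted over the list alone. Since they share windows, the 10 genes are fewer than 10 separate observations. HOXD13 stood at 4.32, and HOXD1 and HOXD10, which share a window, at 4.18. Here scaling mattered, since 8 HOX genes were called earlier in U2OS with interquartile range scaling and 6 in the values as deposited. Of 24 long genes at common fragile sites, 10 were earlier in H9 and 2 in U2OS, as when adjusted over the list alone (10 and 1 without either U2OS track). MAGI2 differed by 4.53 and AUTS2 by 3.99, against -0.04 for PTPRD (adjusted p = 0.806). Of 21 housekeeping genes, 15 were not called, 2 were earlier in H9 and 4 in U2OS, the same adjusted over the list alone (2 and 7 without H9 replicate 2), with TBP at -2.74 (adjusted p = 0.000126) and RAB7A at -0.03 (adjusted p = 0.876). With interquartile range scaling, 14 housekeeping genes were earlier in U2OS.

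The zinc finger genes of chromosome 19 made up the list with the most one-sided calls among large lists. Of 250 such genes, 149 were earlier in H9, 37 earlier in U2OS and 64 not called (149 and 40 adjusted over the list alone; 139 and 67 with interquartile range scaling). Their median timing was 2.99 in H9 and -0.24 in U2OS. ZNF486 differed by 7.27 (SE 0.28, adjusted p = 4.25e-05) and the neighbours ZNF682 and ZNF90 by 7.13, while ZNF441 stood at 0.06 (adjusted p = 0.642), or -0.54 with interquartile range scaling. Of 384 olfactory receptor genes, 137 were earlier in H9 and 76 in U2OS, as when adjusted over the list alone, with OR10T2 at 4.15, OR10K1 and OR10K2 at 3.81 and OR4C46 at 0.02 (adjusted p = 0.913). For comparison, 4453 of all 19001 measured genes were earlier in H9 and 5280 earlier in U2OS. In camera's test of the midpoint windows of each list against all other windows, only the zinc finger list passed, toward H9 (adjusted p = 2.2e-05). It did not pass with an estimated correlation (adjusted p = 0.2045). The other 10 lists had adjusted p from 0.145 to 0.779. For the HOX and pluripotency lists, the median over windows (-0.16 and -0.03) had the opposite sign of the mean (1.19 and 0.77) and of the test. With the windows of whole gene bodies, camera also passed fragile site genes toward H9 (adjusted p = 0.000339) and mesenchymal genes toward U2OS (adjusted p = 0.00555). Neither passed with an estimated correlation (camera adjusted p = 0.0882 and 0.418).

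**Figure D2:**
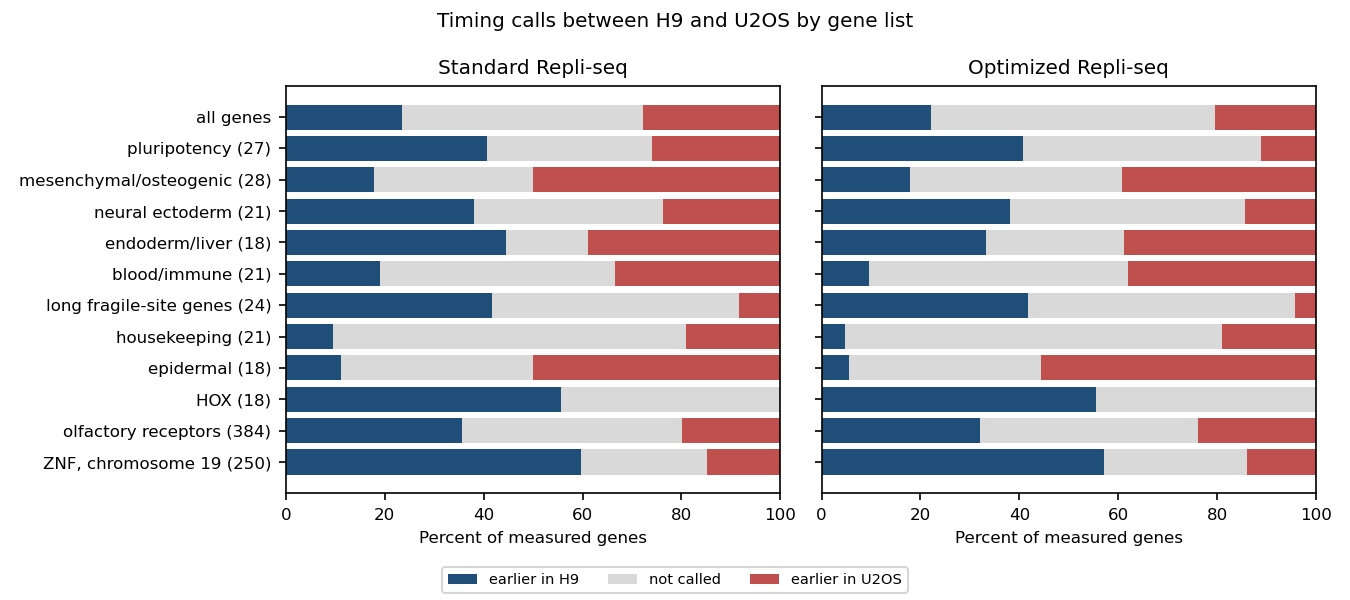
Percent of the measured genes of each list (horizontal axis) called earlier in H9, earlier in U2OS or not called, for the standard and the optimized tracks. The zinc finger list has 149 of its 250 genes earlier in H9 in the standard tracks, against 4453 of all 19001 genes.

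The same comparison in optimized tracks set 2 H9 tracks of 40000 cells against 3 U2OS tracks. SOX2 differed by 7.27, OTX2 by 7.42, ZNF486 by 7.41, PRDM14 by 6.81 and DPPA2 by 6.48 toward H9. Toward U2OS, RUNX1 differed by -7.20, VIM by -5.83, PTPRC by -5.80, COL3A1 by -5.50, FLG by -5.28 and NEUROG1 by -5.13. The TGFB2 region averaged -4.29 ± 0.02 (SD, n = 2) in H9 and 1.66 ± 0.36 (SD, n = 3) in U2OS, and the GLCCI1 region 1.32 ± 0.05 and -3.32 ± 0.02. All 10 named regions kept their direction, with 13 of 13 windows of the OTX2 region, 19 of 19 of the TGFB2 region and 18 of 20 of the GLCCI1 region called. In total, limma called 15107 of 27098 windows, 55.7%, with 7511 earlier in H9 and 7596 in U2OS. Interquartile range scaling moved the median difference of all windows from 0.01 to -0.11 here. The pluripotency list had 11 genes earlier in H9 and 3 in U2OS (10 and 3 adjusted over the list alone), and the mesenchymal list 5 and 11. Further counts toward H9 and U2OS were 8 and 3 for neural, 6 and 7 for endoderm, 2 and 8 for blood (2 and 7 adjusted over the list alone), 1 and 10 for epidermal and 10 and 0 for HOX genes. Fragile site genes had 10 and 1, housekeeping genes 1 and 4, olfactory receptor genes 123 and 92 (123 and 95 adjusted over the list alone) and zinc finger genes 143 and 35 (144 and 35 adjusted over the list alone). Unless given, the count adjusted over the list alone was the same. With interquartile range scaling the HOX counts were 10 and 3. Leaving out 1 track changed them to 6 and 0 (40000-cell replicate 1 or U2OS replicate 3) or 6 and 2 (40000-cell replicate 2), the neural count toward H9 to 5 and the olfactory receptor count toward U2OS to 54 (both 40000-cell replicate 2), and counts of 4 or fewer moved by up to 3. By camera on midpoint windows only the zinc finger list passed (adjusted p = 9.39e-06), and it did not with an estimated correlation (adjusted p = 0.6372). For the HOX list the median over windows (-0.06) and the mean (1.28) differed in sign, and for housekeeping genes the mean (0.01) and the test did. With whole gene bodies, camera also passed fragile site genes toward H9 (adjusted p = 0.000366). It passed epidermal and blood genes toward U2OS (adjusted p = 0.0273 and 0.0380). None of these 3 lists passed with an estimated correlation (camera adjusted p = 0.0582, 0.4293 and 0.4293).

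A test of the interaction of cell line and protocol called 18 of 27070 windows by limma, 12 with a larger H9 minus U2OS difference in optimized tracks and 6 with a smaller one. None of the named genes or regions was among them. ACTB, the housekeeping gene of cytoplasmic actin, was later in H9 in the standard tracks (-1.51, SE 0.35, adjusted p = 0.0172) and was not called in the optimized tracks (0.58, adjusted p = 0.228), and its interaction did not pass (2.16, adjusted p = 0.32). The called windows held TJP1, a tight junction gene, and GOLGA8J on chromosome 15 from 29700001 to 30100000, where U2OS stood at 0.68 ± 0.46 by the standard and 3.61 ± 0.13 by the optimized protocol. Of the 18 windows, 15 lay where the U2OS standard tracks ran in nearly straight lines. Leaving out U2OS optimized replicate 1 gave 4.44% of windows, and leaving out either H9 optimized or either H9 standard track, or U2OS optimized replicate 2 or 3, gave 0.

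Within H9, the protocols gave values close to each other at some named genes and apart at others. SOX2 stood at 3.26 ± 0.26 by the standard and 3.05 ± 0.18 by the optimized protocol with 40000 cells (SD, n = 2 each), OTX2 at 3.81 ± 0.39 and 3.92 ± 0.15, and RUNX1 at -3.66 ± 0.01 and -3.99 ± 0.18. ACTB moved most, from 2.41 ± 0.65 to 3.89 ± 0.19, and was not called (fitted difference 1.49, SE 0.33, adjusted p = 0.266). The largest shift of a named region was -0.53, at GLCCI1. In U2OS, SOX2 stood at -4.30 ± 0.09 and -4.27 ± 0.23 and VIM at 3.55 ± 0.00 and 3.63 ± 0.23 (SD, n = 2 and 3). By limma, 0 of 27071 windows were called in H9 (3184 at an unadjusted p below 0.05) and 0 of 27075 in U2OS (577 at an unadjusted p below 0.05). The SD of the difference over windows was 0.283 and 0.314. With no true difference, a share of about 0.05 of windows would pass the unadjusted threshold. The share was above this in H9 and below it in U2OS. Neighbouring windows are not independent, and neither share was tested. The counts of 0 do not show that the protocols gave equal timing, and a difference spread over many H9 windows stays open. Leaving out 1 H9 standard track called 2.56% (replicate 1) or 15.5% (replicate 2) of windows, where the lone standard track was assumed to vary like the tightly matching tracks of 40000 cells.

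Mean shifts of gene lists between protocols were small. No list passed camera with an estimated correlation, or fry's directional test (lowest adjusted p = 0.1714). Fry's mixed test, which ignores direction, passed for blood and fragile site genes in H9 (adjusted p = 0.000731 and 0.0113). It also passed for endoderm genes in U2OS (adjusted p = 1.665e-05). With whole gene bodies, neither H9 list passed the mixed test (fry adjusted p = 0.0780 and 0.0524). In H9, pluripotency genes were on average 0.25 earlier by the optimized protocol (camera adjusted p = 0.0013; adjusted p = 0.4408 with an estimated correlation). Adjusted over the list alone, 3 of them were called, chosen for naming after their values were seen: DNMT3B, a DNA methyltransferase (0.95), TERF1, a telomere protein (0.59), and PODXL (0.98). The shift is not shown to be particular to this list. Housekeeping windows moved the same way, by a mean of 0.20 (camera adjusted p = 0.111). The median of windows with 5 or more genes went from 3.21 ± 0.30 to 3.84 ± 0.08 (SD, n = 2 each). Olfactory receptor windows had a mean of -0.12, toward later by the optimized protocol (camera adjusted p = 0.00646, and 0.4408 with an estimated correlation). No member was called later, and the 1 called when adjusted over the list alone, OR2A1, was earlier at 1.04. In U2OS, zinc finger genes had a mean of -0.19 (adjusted p = 1.449e-07) and neural genes a mean of -0.19 (adjusted p = 0.0459), both with an adjusted p = 0.5742 with an estimated correlation. On chromosome 19 the U2OS optimized tracks lay apart, at 1.855 ± 0.340 (SD, n = 3), a spread wider than the zinc finger shift. Adjusted over the list alone, 16 olfactory receptor genes were called later in U2OS by the optimized protocol. All of these but OR4F16 and OR11H1 lay on chromosome 6 between 29044213 and 29590500, where the U2OS standard tracks were far apart (OR11A1 at 4.64 ± 2.20). With midpoint windows, no other list of the 11 passed camera with the preset correlation. With whole gene bodies, epidermal genes in H9 (camera adjusted p = 0.04595) and HOX genes in U2OS (camera adjusted p = 0.04938) passed too. Neither did with an estimated correlation (camera adjusted p = 0.6003 and 0.4768).

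In MEF, the standard track correlated at 0.995 with each optimized track over 22973 windows, and the optimized replicates with each other at 0.997. The SD of the difference was 0.303 and 0.306 against 0.242 between the replicates. By limma, 0 of 22973 windows were called (1907 at an unadjusted p below 0.05), with 1 standard track and no check of its own spread. Of 19 gaps over 1 Mb in the mouse positions, 16 had the same edges as gaps in the human tables.

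The titration asked how few H9 cells keep the profile. The TGFB2 region averaged -4.07 ± 0.39 with 100 cells (SD, n = 3) against -4.29 ± 0.02 with 40000 cells (SD, n = 2), the OTX2 region 2.29 ± 0.64 against 2.46 ± 0.00, the RUNX1 region -1.52 ± 0.36 against -1.98 ± 0.01 and the GLCCI1 region 1.17 ± 0.67 against 1.32 ± 0.05. Against 40000 cells, limma called 0 of 27101 windows with 10000 cells (203 at an unadjusted p below 0.05), 0 with 1000 (2682), 0 with 500 (3841) and 0 with 100 cells (912). A share of about 0.05 of windows would pass the unadjusted threshold with no true difference. The share was above this with 1000 and 500 cells and below it with 10000 and 100 cells, which was not tested. These counts of 0 do not show that timing was equal to that with 40000 cells. Leaving out 1 track of the lower number called 23.1 or 15.9% of windows with 10000 cells, 26.9 or 38.8% with 1000 and 30.3 or 41.3% with 500, where the remaining track was alone, as with 5000 cells. With 100 cells, any 1 track left out gave 0. The spread with 10000 cells comes from a pair whose replicate 1 was nearly identical to a standard track, as given below. With 20000 cells, 4 windows were called (1100 at an unadjusted p below 0.05): 1 on chromosome 9 at 43400001 (-1.66), 1 on chromosome 20 at 29900001 (1.55) and 2 on chromosome 21 from 6700001 to 6900000 (-1.50). None of these held a protein-coding gene, and leaving out either track of 40000 cells called 0, while leaving out 20000-cell replicate 1 or 2 called 44 or 41. With 5000 cells, 7085 windows (26.1%) were called, for a single track assumed to vary like the tracks of 40000 cells.

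Correlation with the mean of the standard tracks was 0.994 with 40000 cells, 0.995 with 20000, 0.986 ± 0.017 with 10000, 0.971 with 5000, 0.960 ± 0.018 with 1000, 0.958 ± 0.017 with 500 and 0.972 ± 0.022 with 100 cells. The 100-cell tracks stood at 0.985, 0.986 and 0.947. The 10000-cell replicate 1 was nearly identical to standard replicate 1 (r = 0.999, SD of the difference 0.113, against 0.236 for the next closest tracks), so its value says little of cell number. Over the 14 tracks the correlation rose with log cell number (r = 0.591, permutation p = 0.0291, adjusted p = 0.0388; rho = 0.639, p = 0.0164). Leaving out 2 of the 100-cell tracks, the farthest from the median, gave r from 0.621 to 0.876, each past the threshold (highest p = 0.0316), as did leaving out all 3 (r = 0.845, p = 0.00115). With 1 track left out, r missed the threshold without 40000-cell replicate 1 or 2 or 100-cell replicate 3 (r = 0.549, 0.552 and 0.501; permutation p = 0.0534, 0.0517 and 0.0829), while rho passed without each (p = 0.0353, 0.0325 and 0.0325).

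The SD of the difference of a track from the mean of the other tracks of its group rose from 0.222 with 40000 and 0.241 with 20000 cells to 0.760 with 10000, 0.762 with 1000, 0.777 with 500 and, as the mean over 3 tracks, 0.898 with 100 cells. For 2 tracks this is the SD of their difference, while for 3 the averaging of the other tracks lowers it; as a mean over pairs, the value with 100 cells was 1.03. The 10000-cell value may not be scatter between 10000-cell replicates, since replicate 1 was nearly identical to standard replicate 1. Over these 6 groups r was -0.848 (exact permutation p = 0.0208, adjusted p = 0.0388; rho = -1, p = 0.00278), and with means over pairs -0.886 (exact permutation p = 0.00556). Without the 10000-cell group r was -0.981 (exact permutation p = 0.00833). With chromosome X included or quantile-normalized tracks r passed (-0.837 and -0.841; p = 0.0333 and 0.0319) and rho did not (-0.829 and -0.771; p = 0.0583 and 0.103). Without the 2 farthest groups r was -0.708 and no longer passed (exact permutation p = 0.0833), and r did not pass without 100-cell replicate 3 (r = -0.721, exact permutation p = 0.149) or without the 40000-cell group (r = -0.769, exact permutation p = 0.075), the 1000-cell group (r = -0.840, exact permutation p = 0.108) or the 500-cell group (r = -0.835, exact permutation p = 0.108). In the last 3 of these rho stayed at -1 (p = 0.0167), while without 100-cell replicate 3 it was -0.657 (p = 0.175). The range from the 5th to the 95th percentile narrowed from 8.56 with 40000 cells to 7.83 ± 0.32 with 1000, 7.72 ± 0.38 with 500 and 7.86 ± 0.75 with 100 cells (r = 0.671, permutation p = 0.00694, adjusted p = 0.0278; rho = 0.821). Leaving out 2 of the 100-cell tracks gave r from 0.695 to 0.931. The SD of the step between adjacent positions showed no relation that passed (r = 0.377, permutation p = 0.196; rho = 0.364, p = 0.202). Divided by the interquartile range it had the opposite sign and did not pass either (r = -0.280, p = 0.326; rho = -0.415, p = 0.139). Undivided, r was from 0.181 to 0.330 without 2 or all 3 of the 100-cell tracks. Tracks fell into sets with values at the same positions. Within the 6 tracks of 10000 cells or more and the 7 of 1000 or fewer, r was 0.417 (exact permutation p = 0.644) and -0.364 (p = 0.424) for the correlation with the standard, 0.766 (p = 0.0444) and -0.07 (p = 0.905) for the range, and -0.783 (p = 0.0222) and 0.158 (p = 0.686) for the step. The relations thus did not hold within both sets, and scatter had too few groups per set.

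**Figure D3:**
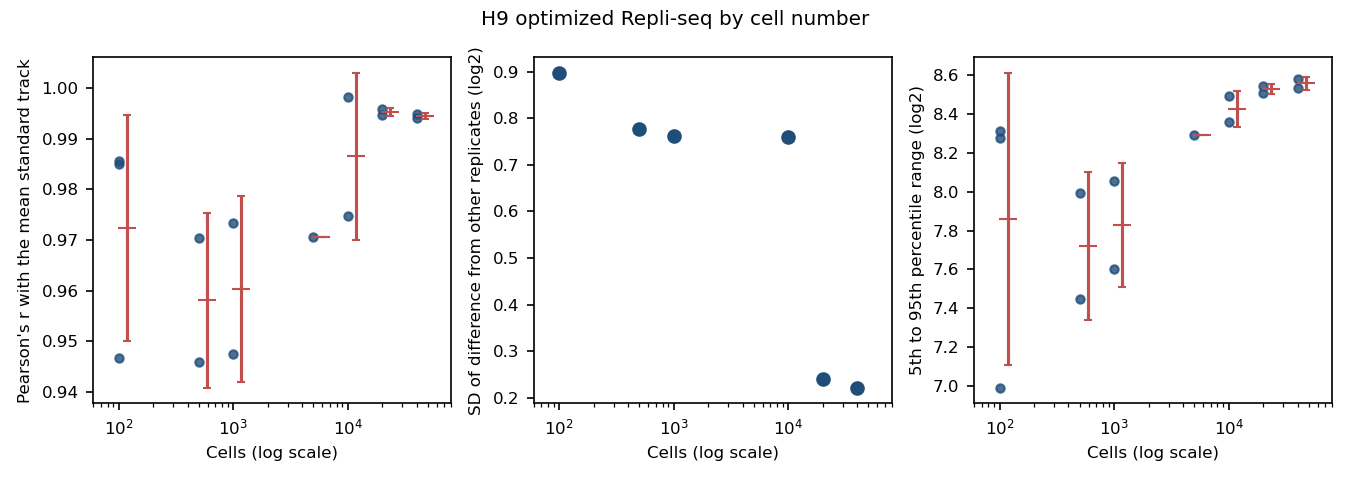
Correlation with the standard tracks (left), SD of the difference of a track from the mean of the other tracks of its group (middle, 1 mean per group) and range from the 5th to the 95th percentile (right) of the optimized H9 tracks against the number of cells (log axis); points on the left and right are tracks, dashes group means and bars SDs. Correlation with the standard tracks falls from 0.994 with 40000 cells to 0.958 with 500, and the 100-cell tracks lie at 0.985, 0.986 and 0.947.

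Differences between H9 and U2OS were then set against those of the standard tracks at each cell number. Of the windows called in standard tracks, 97.1% had the same sign with 40000 cells, 97.7% with 20000, 98.5% with 10000, 91.2% with 5000, 93.4% with 1000, 91.6% with 500 and 96.3% with 100 cells. Called again with the same sign were 85.2%, 85.3%, 77.9%, 69.5%, 69.8%, 69.1% and 67.0% in that order. Among windows not called in standard tracks, 12.2%, 11.3%, 4.01%, 23.2%, 13.6%, 18.4% and 4.18% were called. Of the windows that differed by at least 2 in standard tracks, 98.7% were called again with 40000 cells, 94.6% with 1000 and 94.7% with 500. With 100 cells, 5488 windows were called earlier in H9 in both comparisons, against 1701 for independent lists, and 5321 earlier in U2OS, against 1663. These comparisons share no track with the standard one, apart from the nearly identical 10000-cell replicate, and all optimized comparisons share the 3 U2OS tracks.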

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

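The tests of nearly straight stretches were chosen only after the interaction was seen, while the interaction itself was planned. Timing differed between protocols by cell line in 18 windows, which form 8 regions. These calls were lost with the replicate block and when any single H9 track of the fit was left out. The H9 minus U2OS difference was larger in optimized than in standard tracks by 5.15 on chromosome 6 at 29400001 (OR11A1, OR10C1, OR2H1, MAS1L), by 2.25 on chromosome 9 from 67700001 to 67900000 (ANKRD20A1), by 3.54 on chromosome 14 from 106000001 to 106500000, by 1.90 on chromosome 15 from 31900001 to 32100000, by 1.67 on chromosome 22 at 12400001 and by 1.52 on chromosome 22 at 23900001 (DDT, DDTL, GSTT2B, GSTT4). It changed by -3.35 on chromosome 15 from 29700001 to 30100000 (TJP1, GOLGA8J) and by -2.14 in 1 further region. The smallest adjusted p of a region was 0.0281, except 0.0356 on chromosome 22 at 12400001. These genes were named because their windows were called, not by the rule for named genes.

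In most of these windows the standard U2OS tracks stood apart, as on chromosome 14, where U2OS averaged 0.08 ± 0.37 by the standard protocol (SD, n = 2) and -3.53 ± 0.30 by the optimized one (SD, n = 3), against -3.84 ± 0.26 and -4.07 ± 0.04 in H9. A candidate explanation is that stretches with missing values had been filled with straight lines in the U2OS standard tracks: 83.33% of the called windows, 15 of 18, lay in the 5% of windows where those tracks bend least. The other 3, on chromosome 9 and on chromosome 22 at 12400001, lay outside it and stay unexplained. On chromosome 22 at 23900001, U2OS moved little, from 4.22 ± 0.04 by the standard to 3.96 ± 0.10 by the optimized protocol. H9 moved there from 2.82 ± 0.02 to 4.03 ± 0.06. The change in that window thus lay mostly in H9, and straight U2OS stretches alone do not account for it. A like fill-in of the U2OS optimized tracks is argued against, since 0.0% of the called windows lay in their least bent 5%. A difference of the U2OS cultures between protocols stays open and was not tested.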

How the results depend on the processing

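Settings chosen after seeing the data were the minimum difference of 2, the curvature of a track, replicate scatter over pairs, the second reference track, and the fits without the nearly identical 10000-cell track or without nearly straight windows. Of 256 alternative values of the comparisons, 205 kept their direction and side of the threshold or stayed within 1.5 times the main count, 10 lost the call, 1 gained one and 40 moved; where a cause is not named, the cause was not tested. Of 1170 alternative values of single genes, 1145 were the same in this sense, 8 lost a call, 15 gained one and 2 reversed, SPI1 to -0.567 and ZNF441 to -0.538 in the standard tracks with interquartile range scaling, against 0.02 and 0.06. Interquartile range scaling called 0.905% of windows between protocols in H9 (97.6% of them earlier in optimized tracks), 0.0406% in U2OS, 51.26% with 5000 cells (80.2% of them earlier) and 0.02214% with 1000 cells. It moved the median difference of all windows to 0.10 between protocols in H9, 0.40 with 5000, 0.70 with 1000 and 0.63 with 500 cells. The values as deposited called 0.01845% with 1000 cells. Windows of 500 kb called 0.0369% between protocols in U2OS, 0.03688% with 20000 cells, 0.01844% with 100 cells and 0.1662% for the interaction. A minimum difference of 2 called 26.69% between lines in standard tracks, by construction fewer.

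Leaving out 1 track at a time gave 0 to 15.51% of windows between protocols in H9 (2.56% and 15.51% without standard replicates 1 and 2), 0 to 0.2105% in U2OS (highest without optimized replicate 1), and, against 40000 cells, 0 to 0.1624% with 20000 cells, 0 to 23.13% with 10000, 0 to 38.84% with 1000 and 0 to 41.3% with 500. The highest values, except in U2OS, came from fits in which a lone track was assumed to vary like the tracks of 40000 cells. The interaction ranged from 0 to 4.444%, with 0.0332% and 0.137% without U2OS standard replicates 1 and 2. Taking out the nearly straight windows removed 15 of its 18 calls by construction, so the 0.0% left tests nothing. The other 3 kept their differences of 1.67 to 2.50 (SE 0.18 to 0.26) and lost the call only by the adjustment over the remaining windows (adjusted p = 0.187 to 0.189, against 0.0281 to 0.0356). Between lines the range was 51.8 to 64.0% in standard tracks, 44.2 to 61.8% in optimized tracks, 31.44 to 64.77% with 5000 cells and 32.6 to 47.3% with 100 cells. The correlation with the standard gave r of 0.501 to 0.706, scatter -0.981 to -0.721, the range 0.597 to 0.779 and the step 0.294 to 0.467. Without the nearly identical track, r was 0.570 for the correlation with the standard, -0.981 for scatter and 0.657 for the range. Scatter as a mean over pairs gave -0.886. The step divided by the interquartile range gave r = -0.280 (permutation p = 0.326), and curvature in its place r = 0.578 (permutation p = 0.0279). Of 44 list tests, 6 passed with camera's preset correlation, 0 with the estimated one and 13 with the preset one on windows of whole gene bodies. With fry's directional test, which does not compare a list with other windows, 19 passed.

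Deviations of same-numbered tracks from their group means correlated only from -0.283 to 0.163. This gave little sign of pairing by replicate number, but it does not show that the cultures were separate. With the replicate block, the interaction called 0.0% of windows, the 20000-cell comparison 0.0738% and the line comparison with 1000 cells 30.92%, each moved by over 1.5 times; the line comparison in optimized tracks gave 46.7%, and no other count moved by over 1.5 times. No track could be left out in MEF, nor the lone 5000-cell track. A pseudocount and a minimum of reads could not be tried, because the values are ratios, and depth therefore limits the precision to an unknown degree.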

Other observations

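All tests of explanations in this part were chosen only after the results were seen. Chromosomes differed in how their timing was shared between the lines. On chromosome 21, 38.0% of windows were earlier in U2OS and 13.9% earlier in H9 in standard tracks, and 37.1% and 12.9% in optimized tracks. Chromosome 10 also leaned to U2OS, with 37.7% against 24.7% of windows, while chromosome 7 leaned to H9, with 42.7% against 22.7%, both in standard tracks. On chromosomes 19 and 22 the shares of calls differed between the protocols, which was not tested: earlier in H9 and U2OS were 22.4% and 29.0% of chromosome 19 in standard but 22.4% and 12.2% in optimized tracks, and 11.3% and 27.9% of chromosome 22 against 12.1% and 13.9%. The U2OS optimized tracks lay apart there, at 1.855 ± 0.340 on chromosome 19 and 2.111 ± 0.295 on chromosome 22 (SD, n = 3), against 2.085 ± 0.028 and 2.350 ± 0.080 by the standard protocol (SD, n = 2). H9 moved the other way between the standard protocol and the optimized one with 40000 cells (SD, n = 2 each). On chromosome 19 H9 went from 2.138 ± 0.187 to 2.460 ± 0.061. On chromosome 22 H9 went from 1.877 ± 0.109 to 2.181 ± 0.015. The shift between protocols was thus not in U2OS alone. Full switches were rarer than called differences: 1049 windows (3.88%) stood above 1 in H9 and below -1 in U2OS in standard tracks, and 843 (3.11%) the other way. The optimized tracks gave 838 and 813 such windows, of which 813 and 744 were shared with the standard tracks.

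Timing followed gene density in both lines. The 15996 windows with no protein-coding gene had a median timing of -2.53 ± 0.00 in H9 and -2.55 ± 0.04 in U2OS by the standard protocol (SD, n = 2 each), and the 484 windows with 5 or more genes 3.21 ± 0.30 and 3.94 ± 0.05. The optimized protocol gave these 484 windows a median of 3.84 ± 0.08 in H9 with 40000 cells (SD, n = 2). In U2OS the value was 3.68 ± 0.31 (SD, n = 3). Its gap to H9 was smaller than this SD and was not tested, so the order of the lines by the optimized protocol is not settled. Spearman's rho across windows, which are not independent, was 0.495 in H9 and 0.509 in U2OS by the standard protocol. By the optimized protocol rho was 0.520 with 40000 H9 cells, 0.497 in U2OS and 0.493 with 100 H9 cells. In the mouse tables, 8 of 20 chromosomes ended within 200 kb of the human chromosome with the same number.

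The 10000-cell replicate 1 and the standard replicate 1 of H9 were nearly identical (r = 0.999 over 285524 positions). Their deviations from the mean of the other H9 tracks correlated at 0.9766, against 0.7965 for the next closest tracks, so 1 pair of libraries may have been deposited under both labels. A culture shared by all tracks numbered 1 is argued against as the cause of the near identity. The highest such correlation for replicate 1 at 20000 or 40000 cells with standard replicate 1 was 0.6028. Whether these tracks shared a culture is not settled by it. Deviations of replicates 1 and 2 from 20000 cells correlated with those of standard replicate 1 at 0.603 and 0.484. With 40000 cells the values were 0.492 and 0.424. No biological explanation was tested.

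In 7 optimized H9 tracks the late end was weak, with a 5th percentile from -4.345 to -3.717 against -4.562 with 40000 cells: 10000-cell replicate 2, the 5000-cell track, all tracks of 1000 and 500 cells, and 100-cell replicate 3. Cell number alone is argued against, since 2 of the 3 100-cell tracks reached -4.597 and -4.652. Processing in sets with values at the same positions is argued against only as the sole cause, by a spread of 0.935 within the set of 1000 or fewer cells. That set held most of the weak tracks, while the set of 10000 or more held only 10000-cell replicate 2. A part played by the sets stays open, as the sets also differ in cell number. Within the 6 weak tracks of 500 to 10000 cells, a symmetric loss of contrast in the deposited, scaled values is argued against. These tracks were chosen by their late end, so their late loss was large in part by choice. Their median loss was 0.018 at the early end (the 95th percentile, which did not enter their choice) and 0.518 at the late end, and each lost more at the late end by at least 0.236, against a range of up to 0.036 between the tracks of 40000 cells. In 100-cell replicate 3 such a loss stays open, with 53.92% of its lost range at the late end. Over all 12 tracks of fewer than 40000 cells the late end held 65.74% of the summed loss. The 100-cell replicates 1 and 2, not among the weak tracks, lost only at the early end. Their 95th percentiles were 3.678 and 3.662, against 3.997 with 40000 cells. A difference in library kit or preparation batch could also give the weak late end and stays open, as the labels do not assign kits to samples.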
